A study of Rattus norvegicus with 6 samples.

How the data were processed

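Total RNA of RBL-2H3 cells was extracted with Trizol and sequenced on Illumina libraries, per the labels' protocols. The 6 samples fall into 2 groups by their titles, control and DHC, with 3 replicates each. Per the submitters' processing notes, Trimmomatic 0.36, featureCounts of Subread 1.5.1, edgeR 3.12.1 and the build Rnor_6.0 were used. The aligner, the annotation release and whether counting used strand are not given in the sources used here, so a gene's reads cannot be told from those of an overlapping antisense gene.

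The deposited table gives 1 RPKM value per gene and library for 18286 genes, with each gene's exon coordinates and summed exon length, per the file headers. That these deposited values are RPKM was found from the values. In each column, value times length is a whole multiple of 1 step for 100% of values within 0.01 read. The total of reads implied by the step equals the column's own total of reads. Read numbers per gene and library totals were recovered from this. The values carry no scaling between libraries beyond the total, so a change in a few abundant transcripts moves all others slightly. Values per kilobase also depend on the exon length chosen for the gene. Of the symbols, 22 had been turned into dates, 1 identifier occurred more than once and 58 genes had exons on more than 1 chromosome. Altogether 13093 symbols were found in a RefSeq table of the assembly GRCr8, from which no coordinates were taken.

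The plan was a quasi-likelihood test of counts with scaling by trimmed means. Because the deposited unit is RPKM, the fallback fixed with it was used, limma 3.58.1 with a trended variance on log2(RPKM + 1), in R 4.3.3, for the 10667 genes with a mean of at least 1 RPKM over all 6 libraries, with group as the only term and Benjamini-Hochberg adjustment. The threshold was an adjusted p of 0.05 with no fold minimum. All log2 fold changes, list medians included, are differences on the log2(RPKM + 1) scale, which understate changes of low genes, and values written as N-fold are ratios of mean RPKM. The method was tested on simulated reads of these genes. For this comparison, over 10683 simulated genes that passed the filter, it recovered 71.6% of genes changed 1.5-fold, 97.0% of those changed 2-fold and 100% of those changed 4-fold, and called 11 unchanged genes among 190 calls. The simulation changed 67, 67 and 66 genes, evenly in both directions, with the same dispersion of 0.0047 for all genes. It held no effect of replicate number and far fewer changed genes than were called in the data, so it does not cover these conditions.

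Before the data were examined, 27 gene lists, the 18 target genes and the rule for named genes were fixed. The 23 lists with at least 5 tested members were tested with limma's camera, two-sided, with a preset correlation of 0.01, and again with the correlation estimated from the data, which leaves 4 residual degrees of freedom. The plan named log2 CPM for this test, and log2(RPKM + 1) was used in its place. Named genes were the 12 with the largest change in each direction among genes past the threshold with at least 5 RPM in the higher group and no overlap between the groups, the 6 with the lowest p in each direction under the same conditions, up to 4 members with the lowest p of each list that passed or had at least 3 members past the threshold, and the target genes. Some genes that this rule names are not reported here. Symbols that are only identifiers were counted and not named, and 358 genes past the threshold were of this kind. Further gene lists, used only for closing observations, were made after the data were seen.

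Library totals, the share of the 10 most counted genes and the mitochondrial share were compared with exact two-sided permutation tests. Replicates of a group differed by more than sampling noise, with chi-square per degree of freedom between 4.52 and 15.9, so no library was counted as a repeat of another. The first principal component held 63.2% of the variance and separated the groups, and the second held 12.8% and set the libraries numbered 1 of both groups apart. The alternatives fixed beforehand were median-of-ratios and upper quartile factors, other filters on low values, limma-voom on the recovered reads, robust variance estimation, a replicate block, stricter thresholds, an estimated correlation, limma's fry, and leaving out each library. Pseudocounts of 0.1 and 0.5, scaling by trimmed means, removal of each library's trend on gene length and leaving out both libraries numbered 1 were added after seeing the data. Of these, scaling by trimmed means had belonged to the planned count test, which was not run. A Wald test of counts was also fixed beforehand and was not run, although reads were recovered, and scaling by library totals is what the deposited values already have.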

Results

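The data are RNA-seq profiles of RBL-2H3 cells, a rat basophilic leukemia line that carries the high-affinity IgE receptor FceRI and is used as a model of mast cells. The series asks whether dihydrocoumarin (DHC), a lactone related to coumarin, inhibits IgE-dependent mast cell activation. There were 2 groups, 3 control libraries and 3 libraries from DHC-treated cells. The labels give all 6 samples the same protocol, in which cells were sensitized with 50 ng/ml of IgE against dinitrophenyl for 12 h and stimulated with 100 ng/ml of the antigen DNP-HSA for 4 h. Beyond this shared protocol nothing in them says whether the control cells, whose treatment label is none, received IgE and antigen, and they state neither the dose nor the duration of DHC. The comparison is therefore of DHC against control as labelled, and a lower value with DHC is not by itself a difference between stimulated and resting cells. The control libraries held 30553433, 29084976 and 34170922 reads assigned to genes, and the DHC libraries 29673755, 31299551 and 29190987. At these depths 3 reads correspond to between 0.0878 and 0.103 RPM (reads in a library scaled to its total), a floor that covers counting error only. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

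With DHC, 16 of 23 tested activation-induced genes and 13 of 19 NF-kB genes fell. So did 5 of 7 tested cytokine and chemokine genes (36 listed) and 8 of 14 tested genes of mast cell identity (26 listed). Of 24 tested cholesterol synthesis genes 14 rose. As groups these lists passed with a preset correlation between genes and not with an estimated one (camera adjusted p = 0.0901, 0.0971, 0.105, 0.0971 and 0.341, in that order). The estimates were −0.00174, 0.0518, 0.163, −0.00716 and 0.354 against the preset 0.01, and the test with them leaves 4 residual degrees of freedom. Gata2, a transcription factor of the mast cell lineage, fell from 344.6 ± 10.3 to 69.93 ± 1.9 RPKM (SD, n = 3 per group), 4.93-fold. Gfi1, a transcriptional repressor of blood cells, fell from 121.8 ± 4.41 to 12.16 ± 1.18 RPKM, and Ccdc184, a coiled-coil protein gene, from 145.3 ± 9.7 to 11.85 ± 0.971 RPKM. Psg19, a pregnancy-specific glycoprotein gene, rose from 24.08 ± 3.9 to 125.4 ± 12.2 RPKM, 5.21-fold. Of 10667 genes tested with limma, 1968 were higher and 1717 lower with DHC at an adjusted p below 0.05, 3685 in all. Of these, 70 were higher and 189 lower by at least 1 on the log2(RPKM + 1) scale. The 3 control and 3 DHC values did not overlap in 49.7% of all genes tested, where chance gives 10%. The split between directions depended on the scaling, with 1285 higher and 2114 lower when libraries were scaled by trimmed means (37.8% higher instead of 53.4%) and 1365 higher and 2048 lower with median-of-ratios factors (40% higher). Without DHC replicate 2, 1201 genes were higher.

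**Figure D1:**
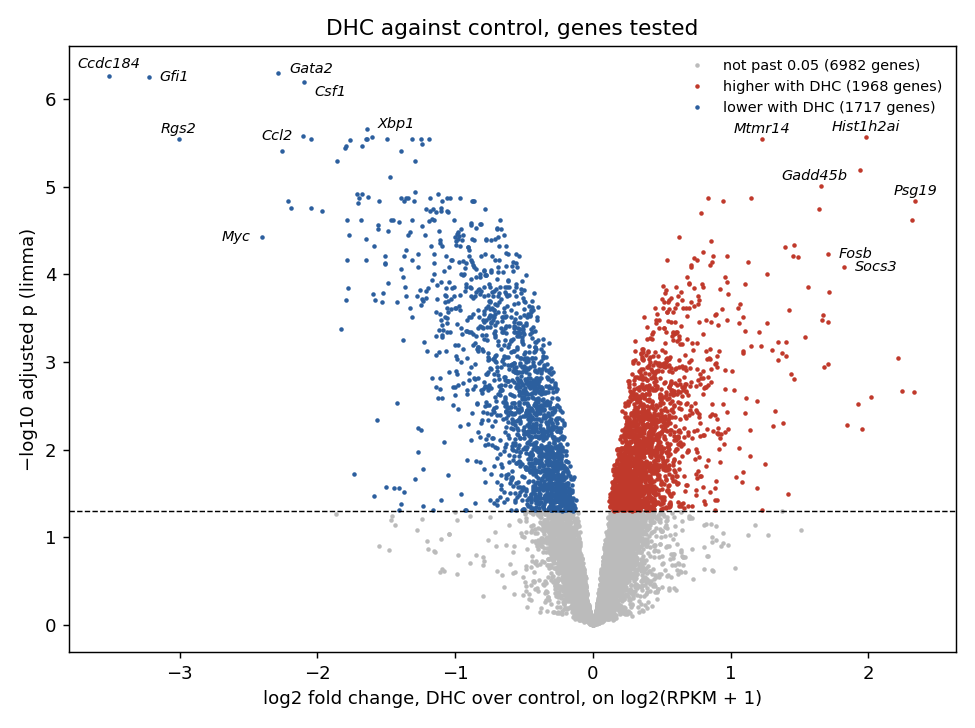
Each point is 1 of the 10667 genes tested, with the log2 fold change of DHC over control on the log2(RPKM + 1) scale on the horizontal axis and −log10 of limma's adjusted p on the vertical axis; the dashed line marks 0.05. The 1968 higher genes are red and the 1717 lower genes blue, and the changes furthest from 0, such as Ccdc184 at −3.51 and Gfi1 at −3.23, were decreases.

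The genes with the lowest p-values among those that fell were Gata2 (log2 fold change −2.28 ± 0.04, SE, limma adjusted p = 5.07e-07), Ccdc184 (−3.51 ± 0.07, 5.4e-07), Gfi1 (−3.23 ± 0.07, 5.59e-07) and Csf1 (−2.10 ± 0.05, 6.27e-07), which encodes a macrophage growth factor. On the rat build Rnor_6.0, Gata2 spans chromosome 4, 120133713 to 120142488, Ccdc184 chromosome 7, 139762614 to 139764013, Gfi1 chromosome 14, 3058993 to 3068371, and Csf1 chromosome 2, 210522375 to 210550560. Each value is over the annotated exons of the whole gene. Rgs2, a regulator of G protein signalling (chromosome 13, 60846308 to 60849094), fell from 807.7 ± 85.8 to 99.85 ± 12.5 RPKM. Myc, a growth-promoting transcription factor, fell from 7.816 ± 1.05 to 0.6732 ± 0.292 RPKM, 11.6-fold, a change that its log2 value of −2.40 understates because of the pseudocount. Gadd45a, a stress-response gene, fell 4.55-fold from 1452 ± 110 RPKM, the chemokine receptor gene Ackr3 5.00-fold from 45.09 ± 1.99 RPKM, the LIM-domain gene Fhl2 4.95-fold and Disp1 4.63-fold. Xbp1, a transcription factor of the unfolded protein response, fell from 464.9 ± 14.4 to 148.5 ± 6.06 RPKM.

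Among the genes that rose, Hist1h2ai, a histone H2A gene (chromosome 17, 44794130 to 44794522), went from 26.64 ± 1.19 to 108.3 ± 6.87 RPKM (log2 fold change 1.98 ± 0.06, limma adjusted p = 2.72e-06). Hist1h1t, a linker histone gene, rose 11.7-fold from 0.6022 ± 0.0872 RPKM, and hist1h2ail2 2.25-fold. Histone genes are near-identical in sequence, so their single values are uncertain where reads could be assigned to more than 1 of them. Socs3, a feedback inhibitor of cytokine signalling, rose from 4.317 ± 0.429 to 17.97 ± 3.45 RPKM, Fosb from 1.127 ± 0.153 to 5.967 ± 0.799 RPKM and Gadd45b from 13.3 ± 1.15 to 44.08 ± 2.01 RPKM. Mtmr14, a phosphoinositide phosphatase gene, rose 2.36-fold, and its relative Mtmr11 6.02-fold from 0.6411 ± 0.0879 RPKM. Brd2, which encodes a bromodomain protein, rose from 52.73 ± 0.608 to 94.7 ± 0.879 RPKM. Ac1576, Gal3st3, Cnnm4, Yif1a, Zfp30 and Cstf3 rose by 4.11-, 2.86-, 3.72-, 3.29-, 4.53- and 1.95-fold.

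Of the 18 receptor, signalling and mediator genes chosen before the data were examined, 14 were tested, 6 fell and 1 rose. None of the receptor's 3 chains passed the test as lower. Fcer1a, the IgE-binding alpha chain, stood at 106.7 ± 4.46 and 109.8 ± 9.46 RPKM (limma adjusted p = 0.7), and Fcer1g, the gamma chain, at 31.83 ± 1.46 and 30.68 ± 4.41 RPKM (0.679). The sign of the Fcer1a difference reversed under scaling by trimmed means and by median-of-ratios factors. Without DHC replicate 3, Fcer1a changed to −0.02 and Fcer1g to 0.06 on the log2 scale. Ms4a2, the beta chain, rose from 320.9 ± 15.9 to 368.5 ± 10.0 RPKM (log2 fold change 0.20, adjusted p = 0.0166), a call that ended under scaling by trimmed means (0.0763) and median-of-ratios factors (0.0608), and without control replicate 2 (0.0619), DHC replicate 2 (0.0603) or DHC replicate 3 (0.0586). Ccl2, a chemokine gene, fell from 48.09 ± 2.75 to 10.43 ± 0.482 RPKM (−2.10 ± 0.06, 2.65e-06), and Ptgs2, the inducible cyclooxygenase gene, from 65.96 ± 3.71 to 13.04 ± 1.52 RPKM (−2.26 ± 0.09, 3.92e-06). Kit, the stem cell factor receptor gene, fell 1.78-fold and Gab2, an adaptor of the receptor, 1.79-fold. Lyn, the first kinase of the pathway, fell 1.23-fold, and Hdc, which makes histamine, 1.24-fold (adjusted p = 0.0183, but 0.0582 without control replicate 2, 0.0545 without control replicate 3 and 0.0671 without DHC replicate 2). Syk was at 7.822 ± 0.438 and 6.54 ± 0.673 RPKM (0.0824), and passed the threshold under scaling by trimmed means (0.0411), by median-of-ratios factors (0.0464) and with limma-voom (0.0225). Lat, Plcg1 and Cpa3 did not pass the threshold (0.263, 0.834 and 0.152). Cpa3 passed it without control replicate 1 (0.0425), and the sign for Plcg1 reversed under scaling by trimmed means and without DHC replicate 1 (−0.01). Il13 was at 2.18 ± 1.48 and 1.379 ± 0.596 RPKM (0.435), with a log2 fold change of −0.35 that became 0.01 without control replicate 1.

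Il4, Tnf and Csf2 lay below the filter on low values. Il4 had 32, 6 and 14 reads in the control libraries and 4, 2 and 6 in the DHC libraries. Tnf had 4, 1 and 2 against 0, 2 and 2 reads, and Csf2 2, 2 and 5 against 0, 0 and 0 reads. With no filter on low values Csf2 passed the threshold (limma adjusted p = 0.0322), and Il4 (0.19) and Tnf (0.651) did not. The Csf2 call rests on at most 5 reads in a library. Il6 had no row under that symbol among the 18286 genes and so could not be analysed.

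**Figure D2:**
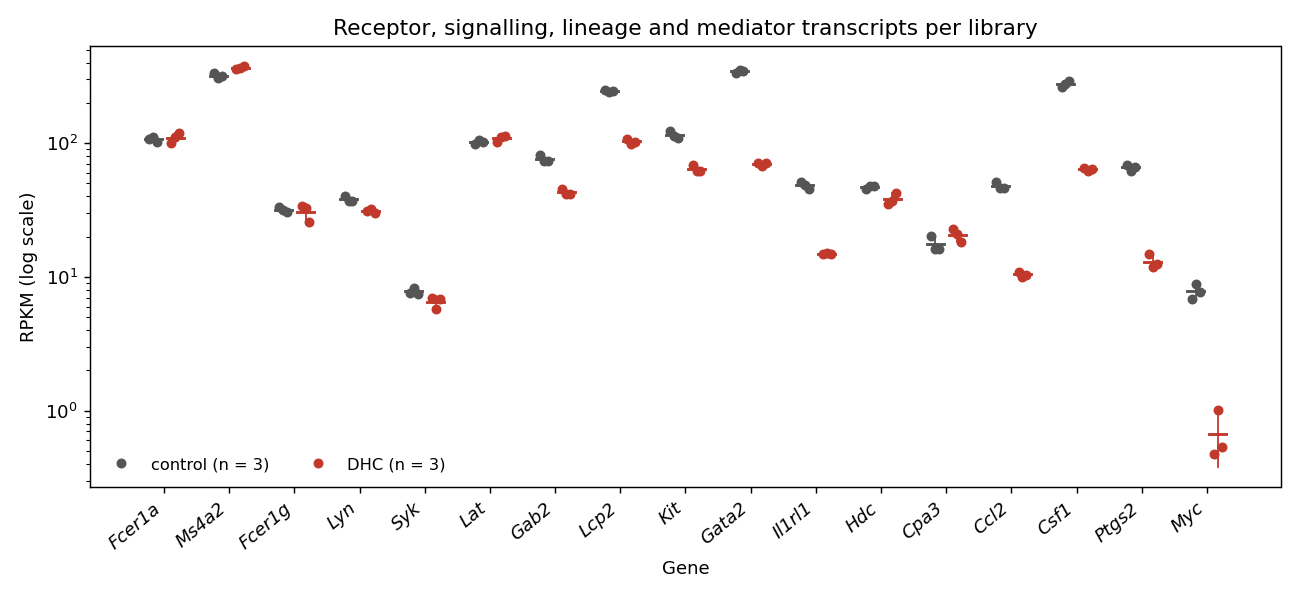
RPKM of receptor, signalling, lineage and mediator genes in each of the 3 control (grey) and 3 DHC (red) libraries, on a log axis; horizontal bars are group means and vertical bars 1 SD. The values for Gata2, Il1rl1, Ccl2, Csf1, Ptgs2 and Myc are separated between the groups, whereas those for Fcer1a overlap.

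Of 23 tested members of the list of immediate early and activation-induced genes, 16 fell and 3 rose, the same numbers when adjusted over the list alone (median log2 fold change −0.68, camera adjusted p = 1.4e-06, and adjusted p = 0.0901 with an estimated correlation). Dusp4, a MAP kinase phosphatase gene, fell from 41.16 ± 3.46 to 10.62 ± 0.461 RPKM, Fosl2 from 37.88 ± 2.92 to 11.56 ± 0.774 RPKM, Bhlhe40 2.48-fold and Klf6 2.40-fold, against the rises of Fosb, Egr3 (log2 fold change 1.09, limma adjusted p = 0.000755) and Egr1 (0.61, 0.02), the last 2 named after their values were seen. Of 19 NF-kB targets and regulators, 13 fell and 3 rose, with 14 lower and 3 higher when adjusted over the list alone (median −0.43, camera adjusted p = 2.82e-05, and adjusted p = 0.0971 with an estimated correlation). Nfkb1 fell 1.86-fold, Birc3, an apoptosis inhibitor gene, 2.12-fold and Nfkbie 2.44-fold, while Irf1, a transcription factor of the interferon response, rose 1.81-fold. Of 36 listed cytokine and chemokine genes 7 were tested. Il4, Tnf and Csf2 were not among them, and Il13 was tested and did not pass. Of the 7 tested 5 fell, also when adjusted over the list alone (median −0.74, camera adjusted p = 5.92e-05, and adjusted p = 0.105 with an estimated correlation). Besides Csf1 and Ccl2 these included Lif, which fell 2.37-fold, and Osm, which fell 1.76-fold.

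Of 14 tested genes of mast cell identity and granule content, 8 fell and none rose at the threshold over all genes, and 8 fell and 1 rose when adjusted over the list alone (median −0.27, camera adjusted p = 0.00102, and adjusted p = 0.0971 with an estimated correlation). After Gata2, the lowest p-values belonged to Il1rl1, the interleukin-33 receptor gene, which fell from 48.47 ± 2.75 to 14.87 ± 0.119 RPKM, Gata1, which fell 2.36-fold, and Kit. Of 31 FceRI signalling genes 13 fell and 4 rose, also when adjusted over the list alone (median −0.18, camera adjusted p = 0.00102, and adjusted p = 0.0971 with an estimated correlation). Lcp2, which encodes the adaptor SLP-76, fell from 246.1 ± 2.81 to 103.2 ± 3.99 RPKM, the lipid phosphatase gene Inpp5d 1.61-fold and the kinase gene Btk 1.37-fold. Of 14 listed aryl hydrocarbon receptor targets 7 were tested, and Cyp1a1, Cyp1a2, Cyp1b1 and Aldh3a1 were not among them. Of the 7 tested 4 fell, 5 when adjusted over the list alone (camera adjusted p = 0.000994, and adjusted p = 0.0971 with an estimated correlation). They were Ahrr, the receptor's repressor (2.69-fold), Ahr itself (2.24-fold), the amino acid transporter gene Slc7a5 (2.09-fold) and Tiparp (1.18-fold), whose call ended without control replicate 1 (0.0851), control replicate 2 (0.0707), control replicate 3 (0.055), DHC replicate 2 (0.105) or DHC replicate 3 (0.0945). Of 10 collagen, matrix and adhesion genes 5 fell, also when adjusted over the list alone (camera adjusted p = 0.000994, and adjusted p = 0.105 with an estimated correlation). Among them were the integrin genes Itga4 (1.77-fold) and Itga5 (1.71-fold) and the adhesion receptor gene Cd44 (1.67-fold), none of which is a collagen.

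Of 24 cholesterol synthesis genes 14 rose and none fell, with 15 higher when adjusted over the list alone (median 0.33, camera adjusted p = 5.92e-05, and adjusted p = 0.341 with an estimated correlation). Insig1, a sterol-regulated gene, rose from 38.86 ± 3.75 to 85.8 ± 6.21 RPKM, Sc5d 1.84-fold and Nsdhl 1.30-fold. Of 23 DNA replication genes 9 rose and 1 fell, 11 and 1 when adjusted over the list alone (median 0.14, camera adjusted p = 0.00835, and adjusted p = 0.233 with an estimated correlation). The median was 0.07 under scaling by trimmed means. Cdt1, which licenses replication origins, rose 1.55-fold, Pcna, the polymerase clamp, 1.36-fold, Fen1 1.27-fold and Gins2 1.27-fold. Without DHC replicate 3, 6 members of this list passed instead of 10. Of 25 nuclear-encoded genes of oxidative phosphorylation 5 rose, a share close to that of the 1968 higher genes among all 10667 tested. As many rose when adjusted over the list alone (median 0.12, camera adjusted p = 0.00936, and adjusted p = 0.204 with an estimated correlation). With limma-voom 9 passed and without both libraries numbered 1, 8. The number was 3 under scaling by trimmed means (median 0.06), under median-of-ratios factors, without control replicate 2 or without DHC replicate 3, and 2 without DHC replicate 2. Cox6c rose 1.30-fold and Ndufs3 1.27-fold. Ndufb5 rose 1.29-fold and Atp5c1 1.14-fold, but neither passed without control replicate 2 (0.0545 and 0.0805), DHC replicate 2 (0.0561 and 0.0771) or DHC replicate 3 (0.0543 and 0.0643). Atp5c1 did not pass under scaling by trimmed means either (0.111).

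Of 12 mitochondrially encoded transcripts, listed as a sign of RNA quality, 5 rose, also when adjusted over the list alone (median 0.23, camera adjusted p = 0.00643, and adjusted p = 0.233 with an estimated correlation). Mt-nd4 rose 1.22-fold, Mt-co1 1.23-fold, Mt-cyb 1.21-fold and Mt-nd4l 1.20-fold. With each library's trend on gene length removed or with no filter on low values, 3 members passed, with limma-voom 9, and without both libraries numbered 1, 8. Mt-nd4l did not pass with the length trend removed (0.0615), nor Mt-co1 with no filter (0.0598). All genes of the mitochondrial chromosome together made up 3.44% ± 0.0955 of the reads in control and 4.00% ± 0.126 in DHC libraries. The 10 most counted genes took 7.02% ± 0.225 and 7.93% ± 0.188. For both shares the exact two-sided permutation p was 0.1, the smallest that 3 against 3 can give. Splits of the 6 libraries that did not follow the treatment gave between 1 and 5 lists past the threshold with the preset correlation. Both groups of each such split mixed control and DHC libraries, so these numbers may hold part of the treatment difference.

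**Figure D3:**
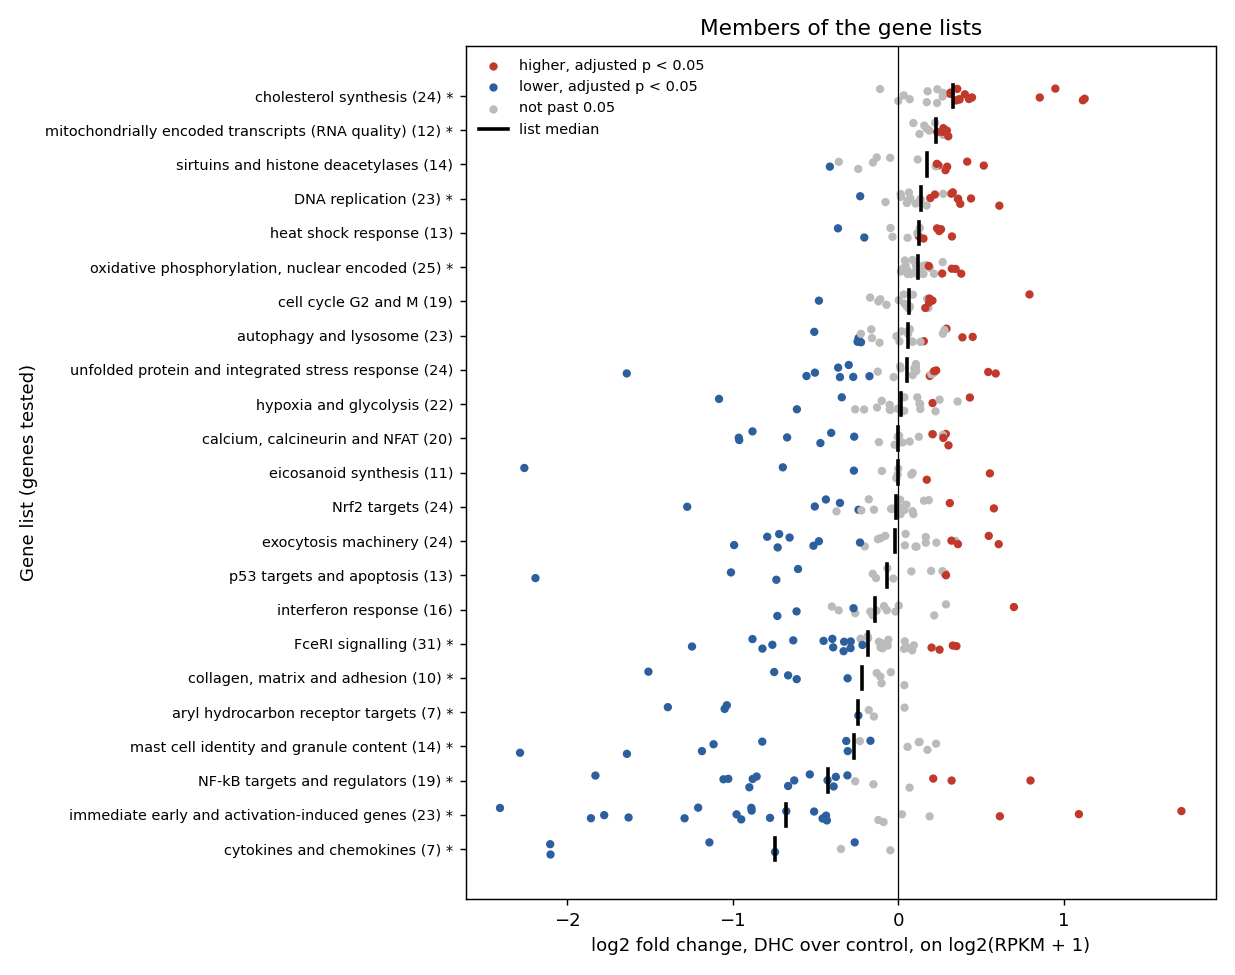
Each row is a gene list with at least 5 tested members (number tested in parentheses) and each point a member, placed by its log2 fold change of DHC over control on the log2(RPKM + 1) scale; black bars are list medians and asterisks mark a camera adjusted p below 0.05 with the preset correlation. Cytokines and chemokines have the lowest median (−0.74) and cholesterol synthesis the highest (0.33).

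The other lists did not pass camera with the preset correlation, except that the p53 list passed as lower with no filter on low values. With limma's fry, which compares a list with no other genes, 8 of them passed. The calcium (adjusted p = 0.00279), eicosanoid (0.000708), exocytosis (0.00272), unfolded protein (0.00299) and p53 lists (0.00299) were lower by it, and the heat shock (0.00742), G2 and M phase (0.0224) and sirtuin lists (0.00197) higher. Their members moved in both directions, but in the p53 list none rose under scaling by trimmed means. Fry was run only on values scaled by library totals, where the median log2 fold change of all genes was 0.05. Under scaling by trimmed means the list medians were 0.06 instead of 0.12 (heat shock), −0.00 instead of 0.06 (G2 and M phase) and 0.11 instead of 0.17 (sirtuins). Of 20 calcium, calcineurin and NFAT genes 4 rose and 7 fell, also when adjusted over the list alone (camera adjusted p = 0.221), and 1 rose and 8 fell under scaling by trimmed means. Orai2, a calcium channel gene, fell 2.09-fold, Nfatc2 2.44-fold, Nfatc1 1.67-fold and Ppp3ca, a calcineurin subunit gene, 1.33-fold. Of 24 exocytosis genes 4 rose and 8 fell, 5 and 9 when adjusted over the list alone (0.153). Snap23, a SNARE protein gene of mast cell degranulation, fell from 563.2 ± 24.0 to 339.3 ± 15.1 RPKM, Stx11 1.76-fold and Rab27a 1.58-fold. Of 11 eicosanoid genes 2 rose and 3 fell, also when adjusted over the list alone (0.435), and 1 rose and 3 fell under scaling by trimmed means. Besides Ptgs2, Pla2g4a, the phospholipase that releases arachidonic acid, fell 1.65-fold and Hpgds, the prostaglandin D synthase gene, 1.21-fold, while Lta4h rose 1.49-fold.

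Stress-response lists were mixed. Of 24 Nrf2 targets 2 rose and 5 fell, also when adjusted over the list alone (camera adjusted p = 0.212). Osgin1 fell 3.25-fold and Txnrd1 1.36-fold, and Gclc rose 1.51-fold and Prdx1 1.24-fold. Of 24 genes of the unfolded protein and integrated stress response 5 rose and 8 fell, 6 and 8 when adjusted over the list alone (0.458), and 2 and 8 under scaling by trimmed means. Hspa5, an endoplasmic reticulum chaperone gene, rose 1.46-fold, and besides Xbp1, Ddit3 fell 1.47-fold and Ddit4 1.43-fold. This list's median was 0.05 while its mean of −0.07 and the test pointed down, and the median became −0.02 under scaling by trimmed means. Of 13 heat shock genes 6 rose and 2 fell, also when adjusted over the list alone (0.203). Hspd1 rose 1.20-fold, Dnaja1 1.19-fold and Hsph1 1.18-fold, and Bag3 fell 1.31-fold. Without control replicate 2, control replicate 3, DHC replicate 2 or DHC replicate 3, or with no filter on low values, 5 heat shock genes passed instead of 8. Of 13 p53 targets and apoptosis genes 2 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.0859, and 0.0382 with no filter on low values). None rose and 6 fell under scaling by trimmed means, and 3 instead of 6 passed without DHC replicate 2. Besides Gadd45a, Cdkn1a, a cell cycle inhibitor gene, fell 1.69-fold, Bcl2l1 2.19-fold and Bcl2 1.86-fold, the last not past the threshold without DHC replicate 2 (0.0517).

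Of 16 interferon response genes 1 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.153), and 7 instead of 4 passed with limma-voom. Stat2 rose 1.70-fold, and Irf9 fell 1.6-fold, Ifit3 2.63-fold and Ifi27 1.22-fold, Ifi27 not passing without control replicate 1 (0.0704), control replicate 2 (0.0527), DHC replicate 1 (0.0609) or DHC replicate 3 (0.0896). Of 22 hypoxia and glycolysis genes 2 rose and 3 fell, 1 and 3 when adjusted over the list alone (0.531), and 1 and 6 under scaling by trimmed means. With limma-voom 9 passed, and with no filter on low values or without control replicate 2, 3. Ndrg1 fell 2.20-fold, Slc2a3 1.54-fold and Hk1 1.27-fold. Ankrd37 rose 1.42-fold but did not pass without control replicate 1 (0.0508), control replicate 2 (0.0594) or DHC replicate 2 (0.067). The median of this list was 0.01 while its mean of −0.04 and the test pointed down, and the median became −0.05 under scaling by trimmed means. Of 19 G2 and M phase genes 5 rose and 1 fell, 4 and 1 when adjusted over the list alone (0.31), and 2 and 1 under scaling by trimmed means, which brought the median from 0.06 to −0.00. Aurkb, a mitotic kinase gene, rose 1.78-fold, Kif11 1.16-fold and Tpx2 1.14-fold (Tpx2 not past the threshold under scaling by trimmed means, 0.0515), and Cenpf fell 1.40-fold. Of 14 sirtuins and histone deacetylases 6 rose and 1 fell, 6 and 2 when adjusted over the list alone (0.439) and 4 and 2 under scaling by trimmed means, and 4 in all passed without control replicate 2 or without DHC replicate 2. Hdac2 rose 1.46-fold, Hdac1 1.18-fold, Hdac5 1.36-fold and Sirt7 1.23-fold, Sirt7 not passing without DHC replicate 2 (0.0611). Of 23 autophagy and lysosome genes 4 rose and 4 fell, also when adjusted over the list alone (0.889), and 5 passed without control replicate 3. Gabarapl1 fell 1.43-fold, and Ulk1 rose 1.48-fold, Atg5 1.32-fold and Map1lc3b 1.23-fold. The median of this list was 0.06, and −0.01 under scaling by trimmed means.

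Markers of other cell types were mostly near 0 RPKM. Too few were tested for a list test. Of 1 tested macrophage gene none passed, of 2 lymphocyte genes 1 rose and of 2 fibroblast and epithelium genes 1 fell. In the basophil, eosinophil, erythroid and platelet list only Pf4, Ppbp and Itga2b were tested, and 1 of these 3 fell. The numbers were the same when adjusted over each list alone. Thy1 fell from 389.7 ± 3.65 to 295.5 ± 6.19 RPKM. Cd3e was at 34.62 ± 2.85 and 41.75 ± 1.69 RPKM (limma adjusted p = 0.0209), with no lymphocyte gene passing under scaling by trimmed means, or without control replicate 2, DHC replicate 2 or DHC replicate 3. Ppbp, a platelet chemokine gene, fell from 3.546 ± 0.36 to 2.214 ± 0.589 RPKM (0.0286), and no gene of its list passed with no filter on low values, or without control replicate 1, control replicate 3, DHC replicate 2 or DHC replicate 3. Pf4, another platelet chemokine gene, was at 1015 ± 87.8 and 1067 ± 106 RPKM.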

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

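Pseudocounts, scaling by trimmed means, length correction and omitting both libraries numbered 1 were chosen as alternatives after seeing the data. Scaling by trimmed means was, however, part of the count test planned beforehand, which was not run. Of 125 named genes tested, 107 kept direction and side of the threshold under all 18 settings they were tested in. At least once, 14 changed side and 4 sign. Most were named for low p or large change, which favours stability. Of all 3685 calls, 2418 (without DHC replicate 2) to 3678 (pseudocount 0.5) recurred. Leaving out 1 library at a time gave 1201 to 1746 higher genes, 1275 to 1609 lower genes, 2476 to 3309 in all, 5 to 8 of the target genes, 4 to 4 higher lists and 7 to 7 lower lists. Scaling by trimmed means kept 3002 calls and gave 1285 higher genes (37.8% of calls, against 53.4%). It moved the median log2 fold change of all genes from 0.05 to −0.00. An adjusted p below 0.01 left 873 higher and 1076 lower genes, 1949 in all, and a log2 fold change of at least 1 left 70 and 189, 259 in all. These follow from the stricter thresholds. The DESeq2 Wald test was not run.

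With an estimated correlation 0 lists passed in either direction, where the adjusted p-values were 0.0901 for immediate early genes, 0.0971 for NF-kB, FceRI signalling, mast cell identity and aryl hydrocarbon receptor lists, 0.105 for cytokines and for collagen, matrix and adhesion, 0.341 for cholesterol synthesis, 0.233 for mitochondrial transcripts and for DNA replication, and 0.204 for oxidative phosphorylation. The unadjusted p was below 0.05 for the 7 lower lists, at most 0.032, and for none of the 4 higher ones. The estimated correlation was below the preset 0.01 for immediate early (−0.00174), mast cell identity (−0.00716), FceRI signalling (−0.0118) and aryl hydrocarbon receptor genes (−0.0528). A higher correlation therefore does not explain why these calls ended, and the test with an estimate leaves 4 residual degrees of freedom. In the other lists that had passed, the estimate was above 0.01, up to 0.354 for cholesterol synthesis. Limma's fry asks if a list's genes move on balance one way and compares them with no others. On values scaled by library totals, the only scaling it was run with, it called 7 lists higher and 12 lower. With no filter on low values 8 lists were lower, with the p53 list added (0.0382; 0.054 to 0.135 when 1 library at a time was left out). The autophagy list reversed its direction under scaling by trimmed means (adjusted p = 0.877), median-of-ratios factors (0.912) and without DHC replicate 2 (0.902), with adjusted p-values of 0.679 to 0.95 when 1 library at a time was left out. Of genes not past the threshold, the log2 fold change reversed for Fcer1a under scaling by trimmed means (−0.028), median-of-ratios factors (−0.018), length correction (−0.006) and without DHC replicate 3 (−0.017; −0.017 to 0.106 over the 6 omissions), for Fcer1g without DHC replicate 3 (0.060; −0.132 to 0.060), for Plcg1 under scaling by trimmed means (−0.004), without both libraries numbered 1 (−0.006) and without DHC replicate 1 (−0.010; −0.010 to 0.071), and for Il13 without control replicate 1 (0.006; −0.635 to 0.006). Beyond the estimated correlations, the cause of these changes was not tested. Depth limits what can be said of Tnf and Csf2, with at most 4 and 5 reads in a library.

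The groups share the replicate numbers 1 to 3, but libraries with the same number did not all deviate together, with correlations of 0.228, −0.0495 and 0.0828, and not every sample correlated best with its own number (control replicate 2 and DHC replicate 3 had 0.106). The second principal component nevertheless placed the numbers alike in both groups, at 12.1, −2.49 and −10.7 in control and 11.5, −2.15 and −8.35 in DHC libraries, a hint from the data and not the design. With the replicate block, 2426 genes were higher and 1907 lower, 4333 in all, with 4 lists higher and 7 lower, and 12 genes each of the oxidative phosphorylation, mitochondrial, and hypoxia and glycolysis lists passed. Among the target genes 8 instead of 7 passed, with Cpa3 added (log2 fold change 0.23, adjusted p = 0.0286).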

Other observations

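All gene lists of this part, and the tests on histone genes and on the bromodomain and ERK explanations, were chosen after the values concerned had been seen. The length tests and the counts of splits were chosen before their results were seen, except that a bootstrap limit was added to the length tests afterwards.

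Of 15 tested transcription factors of blood cell development, Gata2 and Gfi1 among them, 9 fell and none rose (median log2 fold change −1.10, camera adjusted p = 2.45e-09 among the lists of this kind). Fli1 fell from 131.9 ± 1.5 to 52.67 ± 5.72 RPKM (SD, n = 3 per group), Runx3 from 51.32 ± 1.61 to 14.47 ± 0.982, Spi1 from 39.8 ± 1.42 to 18.02 ± 0.869, Tal1 from 32.33 ± 1.66 to 13.69 ± 0.158 and Myb from 24.81 ± 1.3 to 9.068 ± 0.354, while Runx1 was at 4.26 ± 0.0688 and 3.771 ± 0.176 RPKM (limma adjusted p = 0.201). Of 8 regulators of G protein signalling 6 fell (camera adjusted p = 2.73e-05), among them Rgs1 from 738.5 ± 48.0 to 211.7 ± 14.3 RPKM. Of 15 actin cytoskeleton genes 8 fell and 1 rose (0.000102), with Zyx from 174.2 ± 17.6 to 53.78 ± 2.08 and Vcl from 74.15 ± 1.51 to 33.58 ± 1.66 RPKM, and Srf higher at 4.729 ± 0.577 against 3.228 ± 0.502 RPKM. Of 14 cytokine receptor, STAT and SOCS genes 4 rose and 7 fell (0.0704). Csf2rb, the shared beta chain of the interleukin-3 receptor, fell from 244.9 ± 16.2 to 89.18 ± 9.35 RPKM, and Il6st, the shared chain of the interleukin-6 family of receptors, rose from 0.7206 ± 0.335 to 3.345 ± 0.531 RPKM. As these lists were written from genes seen to change, their p-values are descriptions and not independent evidence.

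The 10 splits of the 6 libraries into 3 and 3 are too few for a share below 0.05. The treatment split gave 3685 genes and the highest other split 0, and in both counts 1 split, the real one, was as large. For gene lists the treatment split gave 11 and the highest other 5. Every other split mixed control and DHC libraries within each group, which put the treatment difference into the spread between libraries. Their counts therefore do not show how many genes or lists would pass without a treatment difference.

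Of 25 tested histone genes, taken as those whose symbols begin with Hist, 17 rose and none fell (median log2 fold change 0.56). Reads assigned differently among these near-identical genes would leave their sum as it was, but the lowest DHC library had 1215 RPM over all genes with such symbols and the highest control library 777.6. Any histone copies under other symbols are not in this sum, so reads moved to or from them are not covered. Library composition is argued against by the median of 0.518 that remained under scaling by trimmed means, which shifted all genes by 0.059. A larger share of cells in S phase stays open, since the DNA replication list had a median of 0.135 with a bootstrap upper limit of 0.319, and this limit lies above 0.282, the bound under which S phase would have been excluded as the whole of the rise. A biological effect of DHC on histone transcripts, or on the share that is polyadenylated, was not tested.

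The small rises of 3 lists were set against a trend on gene length, since genes of up to 500 bases had a median log2 fold change of 0.113 and those over 5000 bases 0.026. With each library's trend removed, the camera adjusted p was 0.0395 for mitochondrial transcripts (median 0.164 instead of 0.228, lower limit 0.107), 0.0393 for oxidative phosphorylation (0.102 instead of 0.121, lower limit 0.051) and 0.00425 for DNA replication (0.150 instead of 0.135, lower limit 0.084). The length trend was therefore not the whole of these rises. Whether they reflect RNA quality, cell state or both stays open, and all 3 calls end with an estimated correlation.

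Myc and Myb fell while Brd2 rose, and both a response like that reported for bromodomain (BET) inhibition and lower output of the ERK pathway stay open, because most genes of the first test and all of the second had been seen to change when the lists were written. Of the 5 tested genes of the BET list (median change in the reported direction 0.833, percentile 100 of 10000 random lists matched on expression), 3 are Myc, Myb and Brd2 themselves. After both results were known, the BET test had been narrowed to the 2 members not yet seen, Hexim1 and Serpini1 (percentile 96.93), too few to decide, of which Serpini1 did not pass the threshold (limma adjusted p = 0.0754), and the first versions are given here so that both are read by the same rule. The 3 tested ERK output genes, Phlda1, Dusp4 and Dusp6 (median log2 fold change −1.776, percentile 0), had all been seen to fall. The 23 tested immediate early and activation-induced genes, some of them known to be induced by ERK signalling, went both ways, with 16 lower (Fosl1 at −0.98, Ier3 at −0.95 and Spred1 at −0.89 among them) and 3 higher (Fosb at 1.71, Egr3 at 1.09 and Egr1 at 0.61), and do not decide.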
